A study of Mus musculus with 22 samples.

How the data were processed

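Gene expression was measured with NanoString probes in total RNA from EMT-6 tumours, a mouse mammary carcinoma line grown in the mammary fat pad of BALB/c mice. Per the labels, mice bearing injected tumour cells were randomized at a tumour volume near 100 mm3, and tissue was taken on day 6. NHS-muIL12, an antibody against the DNA and histones of necrotic tissue fused to murine interleukin-12, was injected under the skin at day 0. Avelumab, an antibody against PD-L1, was injected into a vein at 200 µg at days 0, 3 and 6. The 22 libraries, each from 1 mouse, fall into 6 groups, 3 doses of NHS-muIL12 (0, 2 and 10 µg) without or with avelumab. There were 4 mice each with isotype control, 2 µg NHS-muIL12, avelumab plus 2 µg and avelumab plus 10 µg, and 3 mice each with 10 µg NHS-muIL12 and avelumab. The groups with both agents are called combination 2 µg and combination 10 µg. The series text speaks of 4 mice per group, and the other mice are not analysed here.

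The deposited values are NanoString signal on a linear scale, per the labels from a standard protocol. In each library all values above 0 lay within 0.02 of a step of an equally spaced scale, and values stopped at 0. They were therefore read as probe counts from which the authors had subtracted a background and which they had multiplied by a factor for each sample. The software, the background method and the scaling method are not given in the sources used here. The step, in signal per count, ran from 0.664 to 1.68 between libraries, which corresponds to 197653 to 572089 counts above background per library. Because the values were not raw counts, no count model was fitted. Of 770 genes, 20 were on a list of housekeeping genes and 750 were tested. Of the gene names, 756 matched current mouse symbols, 8 matched older synonyms (among them H2-Ea-ps, now H2-Ea) and 6 matched neither. Values at 0 made up 9.44% of the table, and 3 tested genes were at 0 in every library. With no raw counts or replicate hybridizations, the precision of a value was read from the spread between mice alone.

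Values were analysed as log2(signal + 1) in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with default settings; statmod 1.5.0). The model had 1 mean per group and 1 spread for all 22 mice, with 16 residual degrees of freedom. Tests were two-sided, Benjamini-Hochberg adjustment was made within each of 14 comparisons over the 750 genes, and the threshold was an adjusted p under 0.05. The comparisons were 5 groups against isotype, the doses against each other, each combination against its single agents, the interaction at each dose and the avelumab effect averaged over doses. A fold is 2 to the power of the log2 change and, because 1 was added to each value, understates changes in dim genes. No fold is given against a group whose values were all 0. The labels do not pair mice by replicate number, so no pairing was used.

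There were 26 gene lists for cell types and pathways. They were tested with fry, also from limma, which asks whether the genes of a list move on balance in one direction and does not compare the list with other genes. Benjamini-Hochberg adjustment was made over the lists of a comparison. Beside it, camera was run with a preset correlation of 0.01 and with an estimated correlation. Both camera tests compare a list with the remaining genes. With the preset correlation 0 to 11 lists passed, depending on the comparison, and with the estimated correlation 0 lists passed in any of the 14 comparisons. A list score, added after the data were seen, is the mean log2(signal + 1) of a list's measured members in 1 mouse, and its differences carry 95% intervals from the 6-group model. Named genes followed a rule. Against isotype, these were the 12 largest rises and 8 largest falls among genes past the threshold with every treated mouse on the same side of the isotype mean. For other comparisons they were the 5 largest rises and falls past the threshold, or the 2 smallest p where none passed. Up to 4 members of each list with the largest absolute change and a set of genes of the interleukin-12 pathway were also included. The lists, the comparisons, the tests, the rule and the alternatives were fixed before the data were examined, with some exceptions. Chosen later were the list scores, 2 alternatives and the tests of explanations other than the counts for other divisions of the mice.

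The fit was tested on simulated data in which genes were shifted in these groups. At a log2 change of 1, it recovered 76.6% of changed genes brighter than the median gene and 9.43% of the dimmer ones for 10 µg NHS-muIL12 against isotype, and 80.9% and 13.2% for combination 10 µg. At a log2 change of 2 it recovered 100% and 45.3%, and 97.9% and 39.6%. The unchanged genes called were 5 and 4. These rates describe the simulated data only. When the real isotype and 2 µg NHS-muIL12 mice were divided so that each part mixed the groups, up to 162 genes were called. The rates may therefore not carry over to the real data. The alternatives were scaling by the housekeeping genes, centring on each library's median, quantile normalization, leaving out the 25% of genes with the lowest mean, a trended and robust prior, sample weights, a pseudocount of 10, the replicate number as a block, only the groups compared, and leaving out each mouse in turn. Chosen after seeing the data were a pseudocount of 50 and a fit without the 4 libraries with the highest low-end signal. A test on raw counts was planned for that unit and was not run.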

Results

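The data are NanoString signals of 750 tested genes in tumours from 22 mice. Total signal per library ran from 300174 to 511105, with a median of 348679, and the mean log2 signal of the 20 housekeeping genes from 8.79 to 8.91. Pearson's r between libraries, across genes, which are not independent replicates, had a median of 0.947 within groups and 0.935 between groups. Libraries differed at their dim end. The number of genes at 0 ran from 25 to 155, and the lower quartile of signal from 3.36 to 51.5. It was 39.1 and 43.0 in isotype replicates 1 and 2, 51.5 in NHS-muIL12 2 µg replicate 3 and 33.3 in NHS-muIL12 10 µg replicate 3, the 4 highest libraries. The median signal of the 300 genes with a mean under 50 was 30.1 and 37.2 in isotype replicates 1 and 2, 0 and 12.5 in replicates 3 and 4, and 2.27 to 10.6 in the combination groups. The first principal component held 48.2% of the variance and the second 16.6%. On the first, the 4 libraries with the highest lower quartile lay at -42.4 to -23.0, and the other libraries at -14.8 to 21.7.

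NHS-muIL12 at 10 µg was compared with isotype to see what the higher dose alone did to tumour gene expression. Among the largest rises were genes of MHC class II antigen presentation, Slamf7, a receptor of lymphoid and myeloid cells, and an interferon-gamma-induced chemokine. Cxcl9, a chemokine that attracts activated T cells, had a mean signal of 1159 ± 242 (SD, n = 3) against 79.6 ± 57.3 (SD, n = 4) in isotype mice, a log2 rise of 4.05 ± 0.57 (SE), or 16.6-fold. Cd74, the invariant chain of class II molecules, was at 8614 ± 1386 (SD, n = 3) against 762 ± 363 (SD, n = 4), 12.2-fold higher. H2-Aa, a class II alpha chain, was at 5989 ± 1057 (SD, n = 3) against 443 ± 256 (SD, n = 4), 15.6-fold higher. For each of these genes, all 3 mice lay above the highest isotype mouse. In limma with Benjamini-Hochberg adjustment, 79 genes passed, 75 higher and 4 lower, and 170 had an unadjusted p under 0.05. The smallest adjusted p in limma was 7.91e-04, shared by Cxcl9, Cd74, H2-Aa and H2-Eb1.

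Further rises at 10 µg were in H2-Ea-ps (log2 4.39 ± 0.73), H2-Eb1 (3.99 ± 0.60) and H2-Ab1 (3.72 ± 0.58), all of the class II region, and in Fcgr4, an activating Fc receptor (2.81 ± 0.50). Slamf7 (4.12 ± 1.17), Klrk1, which encodes the activating receptor NKG2D (3.48 ± 0.72), Pou2f2 (2.86 ± 0.71) and Klra6 (2.80 ± 0.80) rose from mean signals of 2.15 to 5.55 in isotype mice. Sh2d1a, listed at 0 in all 4 isotype mice, was at 7.19 ± 3.02 (SD, n = 3). Its call was lost in all 7 fits with 1 mouse left out, that of Klra6 in 6 and that of Slamf7 in 4. Cd274, which encodes PD-L1, rose by 1.96 ± 0.51 on the log2 scale. The 4 falls were in Mmp9, a secreted gelatinase (-2.20 ± 0.61), Itgb3, an integrin subunit (-1.42 ± 0.41), F2rl1 (-1.19 ± 0.31) and Dll4, a Notch ligand of sprouting endothelium (-1.14 ± 0.32). These calls were lost in 5, 6, 4 and 5 of the 7 fits with 1 mouse left out, in the same order. Mmp9 in isotype replicate 3 was at 1605 against 640 to 699 in the other isotype mice.

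By gene list, 6 of 26 passed fry at 10 µg, all higher. Of the MHC class II list, 6 of 10 measured members rose, and 7 passed when adjusted over the list alone (fry in limma, adjusted p = 3.23e-04). Of the interferon-gamma response list, 14 of 21 rose, 18 when adjusted over the list alone (fry in limma, adjusted p = 0.00152), with Gbp5 at 2.32 ± 0.44, Cxcl10 at 2.18 ± 0.39 and Irf1 at 1.16 ± 0.27. This list shares 13 members with other lists. Of the lymphocyte chemokine list, 5 of 13 rose, 6 when adjusted over the list alone (fry in limma, adjusted p = 0.00176), with Ccl5 at 2.56 ± 0.53. Of the MHC class I list, 10 of 15 rose, 11 when adjusted over the list alone (fry in limma, adjusted p = 0.00250), with Cd1d1 at 1.61 ± 0.45, H2-T23 at 1.17 ± 0.28 and the immunoproteasome subunit Psmb10 at 1.11 ± 0.18. Of the Fc receptor list, 4 of 5 rose, also when adjusted over the list alone (fry in limma, adjusted p = 0.00566), and of the type I interferon response list 6 of 21, 9 when adjusted over the list alone (fry in limma, adjusted p = 0.0477), with Zbp1 at 1.54 ± 0.34. The Fc receptor list shares Fcgr1 and Fcgr3 with the macrophage list, of which 3 of 19 rose, 7 when adjusted over the list alone (fry in limma, adjusted p = 0.0858). The score of macrophage genes with a mean signal of at least 50 was higher by 0.62 (95% interval 0.02 to 1.22). Over all 19 macrophage genes the difference was 0.49, with an interval that reached 0 (-0.13 to 1.11). With an estimated correlation the adjusted p (camera in limma) was 0.390 for the first 5 lists and 0.773 for the type I interferon list, so no list call was kept. The other lists had adjusted p in fry (limma) from 0.0619 for complement to 0.996.

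The count of 79 was 28 without isotype replicate 2, 23 without NHS-muIL12 10 µg replicate 2, 32 without its replicate 3, 43 after centring on each library's median and 255 with sample weights, and 16 of the 41 named genes past the threshold kept their call whichever mouse was left out, among them Cxcl9, Cd74, H2-Aa, H2-Ab1, H2-Eb1, H2-Ea-ps, Klrk1, Fcgr4, Gbp5, Cxcl10, Ccl5 and Psmb10. Without the 4 libraries of high low-end signal, which leaves 2 isotype and 2 treated mice, limma called 0 genes, with 111 at an unadjusted p under 0.05, and 1 list, while Cxcl9 stood at a log2 change of 3.84, Cd74 at 2.98 and Mmp9 at -2.48.

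**Figure D1:**
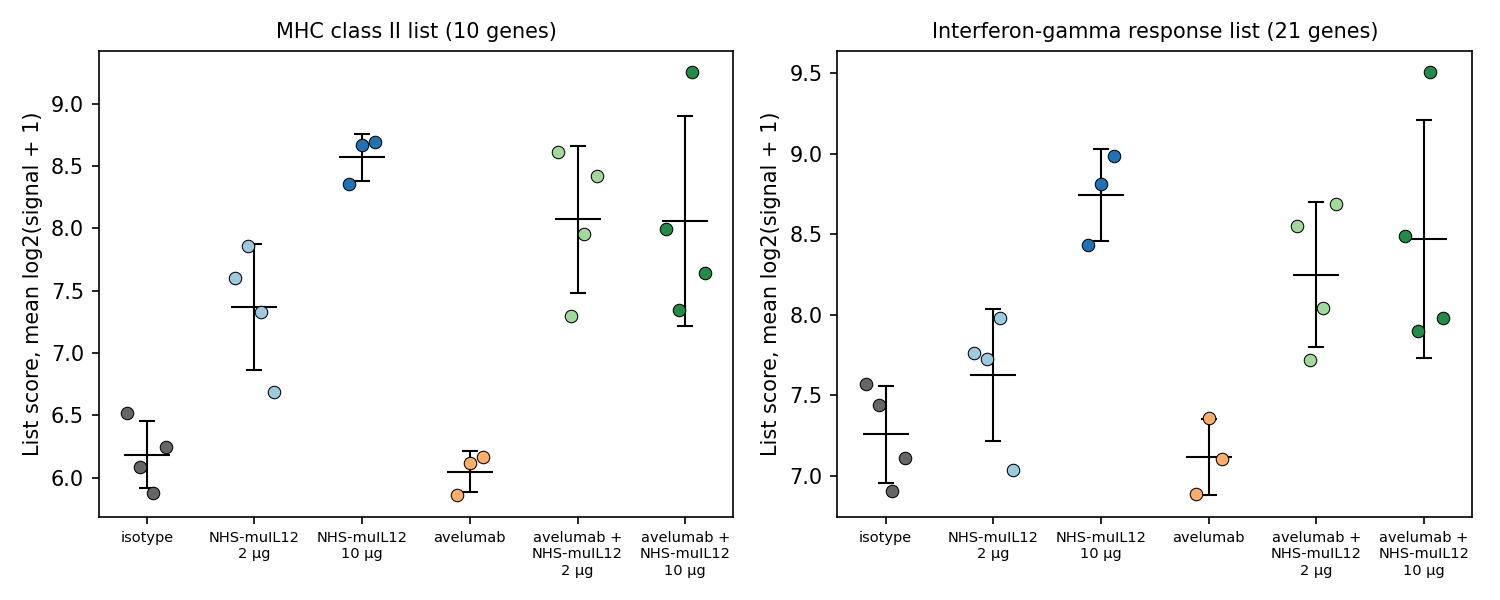
List scores of single mice by treatment group, as the mean log2(signal + 1) of the 10 measured MHC class II genes (left) and the 21 interferon-gamma response genes (right); points are mice, bars are the mean ± SD, and each axis starts above 0. The MHC class II score of every mouse given NHS-muIL12, alone or with avelumab, lay above the highest isotype mouse at 6.52, and those of the 3 mice given avelumab alone did not.

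NHS-muIL12 at 2 µg was compared with isotype to describe the lower dose. No gene passed in limma (0 of 750, with 59 at an unadjusted p under 0.05, smallest adjusted p = 0.0657). Class II genes had higher means that did not pass. Cd74 was at 2822 ± 1289 (SD, n = 4) against 762 ± 363 (SD, n = 4), a log2 change of 1.89 ± 0.50 (limma adjusted p = 0.324), and H2-Aa at 1489 ± 752 (SD, n = 4), a change of 1.86 ± 0.55 (limma adjusted p = 0.324). Cxcl9 was at 236 ± 95.3 (SD, n = 4), a change of 1.69 ± 0.53 (limma adjusted p = 0.324). The MHC class II score was higher by 1.18 (95% interval 0.41 to 1.96), with all 4 mice above the highest isotype mouse. Adjusted over the list alone, 6 of 10 class II genes and 2 of 5 Fc receptor genes passed. No list passed fry (0 of 26, smallest adjusted p in limma 0.0881, for MHC class II, and 0.328 with an estimated correlation). One list passed without NHS-muIL12 2 µg replicate 4, 90 genes passed with sample weights, and without the libraries of high low-end signal limma called 0 genes, with 32 at an unadjusted p under 0.05.

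The 2 doses alone were compared with each other to see the effect of dose. In limma 0 genes passed, with 103 at an unadjusted p under 0.05. The smallest adjusted p, 0.101 in limma, belonged to Gbp5, an interferon-induced GTPase (log2 2.07 ± 0.44), and Gpr183, a chemotactic receptor (-1.14 ± 0.26), neither past the test. The MHC class II score was higher at 10 µg by 1.20 (95% interval 0.37 to 2.04). Without the 4 libraries of high low-end signal it was higher by 1.13, with an interval that reached 0 (-0.03 to 2.29). Lists for MHC class I, the interferon-gamma response and lymphocyte chemokines passed fry (adjusted p = 0.0278 each in limma, and 0.543 with an estimated correlation). None of their members passed over all genes, while 7 of 15, 12 of 21 and 4 of 13 passed when adjusted over the list alone. The 3 list calls fell to 0 without NHS-muIL12 2 µg replicate 1 or 4, without NHS-muIL12 10 µg replicate 2 or 3, after median centring, and without the libraries of high low-end signal, and sample weights gave 63 genes. Without those libraries the score differences were 1.11 for the interferon-gamma response (95% interval 0.16 to 2.07, and 1.12 with all mice), 0.92 for chemokines (0.21 to 1.63, and 0.91) and 0.49 for MHC class I (-0.02 to 1.01, and 0.59).

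Avelumab alone was compared with isotype to describe blockade of PD-L1 by itself. No gene or list passed. Cxcl9 was at 83.3 ± 22.4 (SD, n = 3), Cd74 at 745 ± 295 (SD, n = 3) and H2-Aa at 428 ± 172 (SD, n = 3), close to the isotype means of 79.6, 762 and 443. The MHC class II score differed by -0.13 (95% interval -0.97 to 0.70) and the interferon-gamma response score by -0.14 (-0.87 to 0.59). In limma 0 genes passed, with 38 at an unadjusted p under 0.05 and a smallest adjusted p of 0.611, and 0 lists passed fry, with a smallest adjusted p of 0.619 in limma. Ncr1, an activating receptor of NK cells, was at 9.56 ± 0.67 (SD, n = 3) against 30.2 ± 13.9 (SD, n = 4), a log2 difference of -1.43 ± 0.40 (limma adjusted p = 0.611). Mmp9 was at 381 ± 61.7 (SD, n = 3) against 909 ± 465 (SD, n = 4), a log2 difference of -1.15 ± 0.61 (limma adjusted p = 0.715). All 3 mice lay below the lowest isotype mouse for both genes, for Ccr3, Mst1r, Angpt2, Il15ra and Lyve1, and for 2 list scores, lymphocyte chemokines (-0.32, 95% interval -0.82 to 0.19; 2 of 13 genes lower when adjusted over the list alone) and complement (-0.65, -1.37 to 0.08). They lay above the highest isotype mouse for Pou2f2 and Cdkn1a. Only named genes and the lists were searched for such separation. Mmp9, Ccr3, Mst1r and Angpt2 had been named for falls against the same isotype mice. Il15ra, Lyve1 and Cdkn1a had been named in comparisons that include these avelumab and isotype mice. The number expected by chance was not computed, so the separation is no evidence of an avelumab effect. With sample weights 98 genes passed, 6 higher and 92 lower, and without the libraries of high low-end signal limma called 0 genes, with 37 at an unadjusted p under 0.05.

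Combination 2 µg was compared with isotype. Cxcl9 and 6 of the 10 MHC class II genes rose. Cxcl9 was at 800.4 ± 455 (SD, n = 4) against 79.6 ± 57.3 (SD, n = 4), 10.1-fold higher. Cd74 was at 5822 ± 2558 (SD, n = 4), 7.65-fold higher than isotype, and H2-Aa at 3772 ± 1737 (SD, n = 4), 8.94-fold higher. Tpsab1, a mast cell tryptase, fell, at 3.74 ± 1.95 (SD, n = 4) against 34.5 ± 15.2 (SD, n = 4). In limma 71 genes passed, 58 higher and 13 lower, and 211 had an unadjusted p under 0.05.

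The log2 changes of combination 2 µg were 3.34 ± 0.53 for Cxcl9 (limma adjusted p = 0.00288), 3.43 ± 0.68 for H2-Ea-ps, 3.18 ± 0.56 for H2-Eb1, 3.16 ± 0.55 for H2-Aa, 2.94 ± 0.50 for Cd74 and 2.91 ± 0.54 for H2-Ab1. Slamf7 (4.12 ± 1.09), Pou2f2 (3.55 ± 0.66), Slamf6 (3.44 ± 0.86) and Klrk1 (3.24 ± 0.66) rose from isotype means of 0.875 to 5.55. Fcgr4 (2.25 ± 0.46) and Il10ra, the interleukin-10 receptor (2.10 ± 0.43), also rose. Falls were largest in Ccr3, an eosinophil chemokine receptor (-3.99 ± 1.16), Mst1r (-3.92 ± 0.88), Cma1, a mast cell chymase (-3.56 ± 0.96), Tpsab1 (-2.90 ± 0.57), Mpo (-2.86 ± 0.77), Elk1 (-2.05 ± 0.52), Mmp9 (-1.89 ± 0.57) and Itgb3 (-1.47 ± 0.38). Among these falls only Tpsab1 kept its call whichever mouse was left out. Of the 13 falls, 6 were in genes with a mean signal under 50, whose signal was also higher in isotype replicates 1 and 2 than in the other isotype mice.

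By list, 5 passed fry in combination 2 µg, all higher. Members that rose were 6 of 10 for MHC class II (6 when adjusted over the list alone, fry in limma adjusted p = 0.00170), 11 of 21 for the interferon-gamma response (17 when adjusted over the list alone, 0.0106) and 7 of 15 for MHC class I (10 when adjusted over the list alone, with 1 lower, 0.0106). They were 3 of 5 for Fc receptors (4 when adjusted over the list alone, 0.0141) and 4 of 13 for lymphocyte chemokines (5 when adjusted over the list alone, 0.0328). Cxcl10 was at 1.66 ± 0.36, Gbp5 at 1.75 ± 0.41, Psmb10 at 1.02 ± 0.16 and Fcgr1 at 1.38 ± 0.35. With an estimated correlation the adjusted p (camera in limma) ran from 0.541 for MHC class II to 0.594 for chemokines, so no list call was kept. In the macrophage list 2 of 19 rose, 8 when adjusted over the list alone (fry in limma, adjusted p = 0.121), and the score of its genes with a mean signal of at least 50 was higher by 0.60 (95% interval 0.04 to 1.15). Over all 19 of its genes the difference was 0.27, with an interval that reached 0 (-0.30 to 0.84). In the mast cell and eosinophil list 2 of 7 fell, Tpsab1 and Ccr3 (fry in limma, adjusted p = 0.121), and in the neutrophil list 2 of 13, Mmp9 and Mpo (0.121).

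For combination 2 µg the count of 71 was 26, 19 and 140 without isotype replicates 1, 2 and 3, 16, 45 and 22 without its own replicates 1, 3 and 4, 130 after quantile normalization, 308 with sample weights and 16 with only the 2 groups in the fit, and 13 of 32 named genes past the threshold kept their call whichever mouse was left out. Without the libraries of high low-end signal limma called 0 genes, with 107 at an unadjusted p under 0.05, and 0 lists, while Cxcl9 stood at a log2 change of 3.08, and lists numbered 3 without isotype replicate 2 and 1 without combination 2 µg replicate 4.

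**Figure D2:**
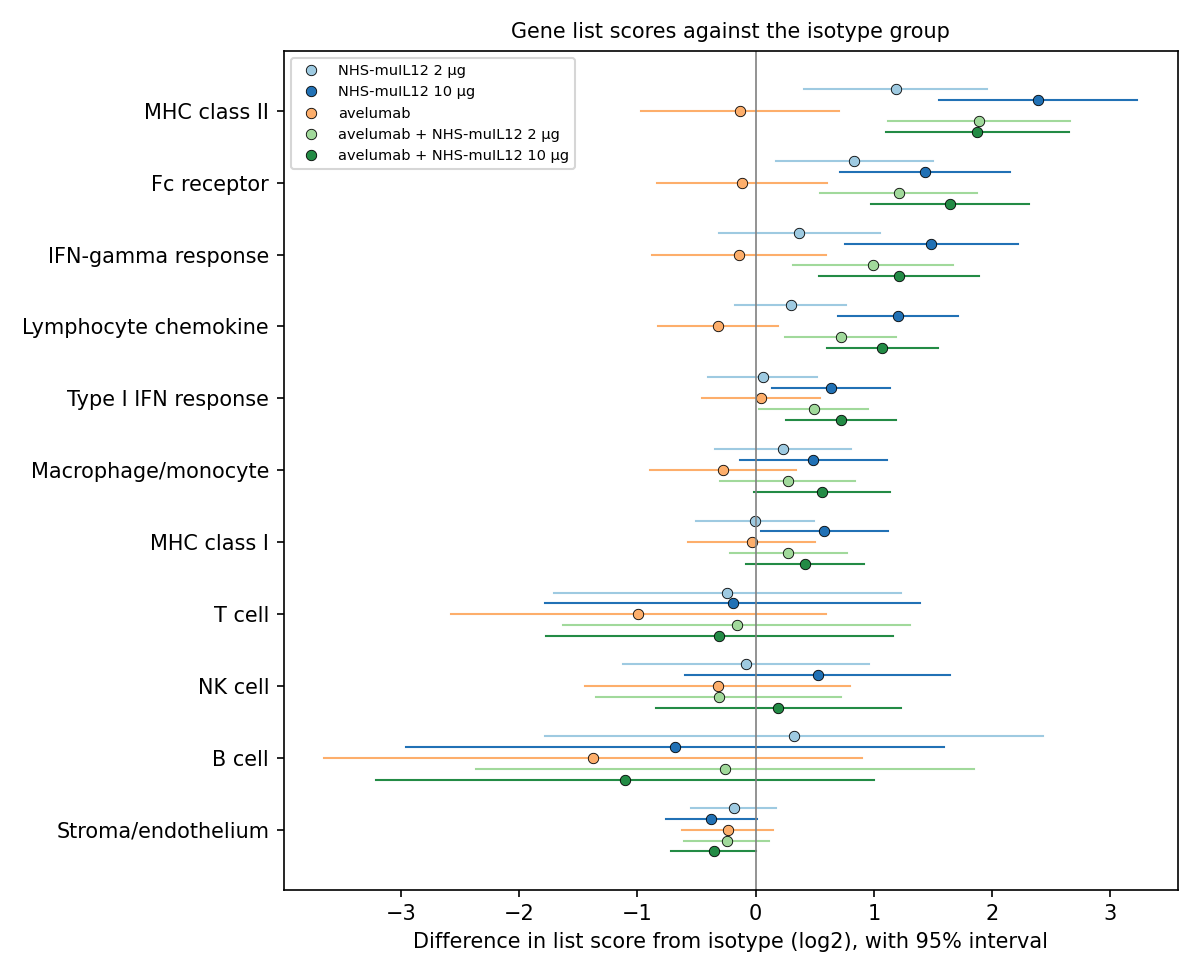
Difference in list score from isotype (log2, horizontal) for 11 gene lists in the 5 treated groups; points are the estimates and lines their 95% intervals from the 6-group model. For MHC class II the estimate was 2.39 with 10 µg NHS-muIL12, 1.89 with combination 2 µg, 1.88 with combination 10 µg and -0.13 with avelumab alone.

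Combination 10 µg was compared with isotype. Genes of the MHC class II, Fc receptor and macrophage lists rose, as did Cxcl9, and Mmp9 fell. Cxcl9 was at 963 ± 768 (SD, n = 4) against 79.6 ± 57.3 (SD, n = 4), 11.4-fold higher. Cd74 was at 7913 ± 6513 (SD, n = 4), 9.01-fold higher than isotype, and H2-Aa at 5483 ± 4801 (SD, n = 4), 11.3-fold higher. Arg1, the arginase of myeloid cells, was at 2348 ± 956 (SD, n = 4) against 809 ± 241 (SD, n = 4), 2.82-fold higher. Mmp9 was at 232 ± 275 (SD, n = 4) against 909 ± 465 (SD, n = 4), a log2 fall of -2.47 ± 0.57. In limma 148 genes passed, 129 higher and 19 lower, and 257 had an unadjusted p under 0.05.

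In combination 10 µg the log2 changes were 3.51 ± 0.53 for Cxcl9, 3.50 ± 0.55 for H2-Aa, 3.40 ± 0.56 for H2-Eb1, 3.27 ± 0.54 for H2-Ab1 and 3.17 ± 0.50 for Cd74 (each limma adjusted p = 8.79e-04), and 3.79 ± 0.68 for H2-Ea-ps. Slamf7 (4.13 ± 1.09), Klrk1 (3.52 ± 0.66), Slamf6 (3.23 ± 0.86), Pou2f2 (3.13 ± 0.66) and Txk (2.99 ± 0.88) rose from dim isotype means of 0.875 to 5.55. Fcgr4 rose by 2.87 ± 0.46, Ccl8 by 2.47 ± 0.65, Cd274 by 1.85 ± 0.47, Gzma, a granzyme of cytotoxic lymphocytes, by 1.60 ± 0.49, and Nos2, the inducible nitric oxide synthase, by 1.39 ± 0.44. Il12rb2, the signalling chain of the interleukin-12 receptor, was listed at 0 in all 4 isotype mice and at 5.41 ± 5.89 (SD, n = 4) here (limma adjusted p = 0.0395), a call lost in 6 of the 8 fits with 1 mouse left out. Besides Mmp9, the largest falls were in Cd207, the langerin gene of dendritic cells (-3.38 ± 0.95), Pnma1 (-3.29 ± 0.98), the mast cell genes Cma1 (-2.91 ± 0.96) and Tpsab1 (-2.03 ± 0.57), Mst1r (-2.89 ± 0.88) and Cspg4 (-2.04 ± 0.67). Each of these calls but that of Mmp9 was lost in 2 to 5 of the 8 fits with 1 mouse left out. Mbl2 was listed at 0 in all 4 mice against 36.4 ± 38.0 (SD, n = 4), with means of 68.8 in isotype replicates 1 and 2 and 3.98 in replicates 3 and 4, and its call was lost in 7 of the 8 fits with 1 mouse left out. Of the 19 falls, 11 were in genes with a mean signal under 50, where isotype replicates 1 and 2 also had more signal than the other isotype mice.

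By list, 7 passed fry in combination 10 µg, all higher. The adjusted p in limma was 0.00136 for each of MHC class I (9 of 15 rose), MHC class II (6 of 10), the interferon-gamma response (17 of 21) and Fc receptors (5 of 5). It was 0.00146 for lymphocyte chemokines (8 of 13), 0.00564 for macrophages and monocytes (10 of 19) and 0.0108 for the type I interferon response (11 of 21). Adjusted over the list alone, 11, 6, 18, 5, 8, 13 and 14 members passed, in the same order. Replicate 3 stood apart in 2 of these list scores, at 8.98 for lymphocyte chemokines against 7.76 to 7.88 in the other mice and at 8.98 for MHC class I against 8.35 to 8.45, and without it 6 lists passed. Psmb10 was at 1.19 ± 0.16, H2-T23 at 1.06 ± 0.26, Gbp5 at 1.90 ± 0.41, Fcgr1 at 1.69 ± 0.35, Cxcl10 at 1.53 ± 0.36, Ccl5 at 1.59 ± 0.49, Zbp1 at 1.58 ± 0.32, Ifi44 at 1.27 ± 0.30 and Irf7 at 1.09 ± 0.29. Chil3, a chitinase-like gene of the macrophage list, was at -2.68 ± 1.41 and did not pass. With an estimated correlation the adjusted p (camera in limma) was 0.459 for the first 5 lists and 0.494 for macrophages and type I interferon, so no list call was kept.

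The 19 other lists did not pass fry in combination 10 µg. The adjusted p in limma was 0.0728 for cell death receptors, 0.0797 for complement, 0.128 for epithelial and proliferation genes, 0.143 for mast cells and eosinophils, and 0.167 for both stroma and endothelium and type 2 and Th17 cytokines. It was 0.271 for the interleukin-12 and Th1 axis, 0.417 for both cytotoxic effectors and neutrophils, 0.457 for both NK cells and B cells, 0.530 for lymph node and 0.588 for CD4 and regulatory T cells. It was 0.773 for both CD8 T cells and costimulation and 0.979 for each of T cells, dendritic cells, inhibitory checkpoints and myeloid inflammation. Several of these lists were mostly dim, with a mean signal under 50 in 12 of 15 T cell, 4 of 4 CD8 T cell, 16 of 19 NK cell, 14 of 15 B cell and 7 of 7 mast cell and eosinophil genes. Changes in them were hard to detect at this signal.

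For combination 10 µg the count of 148 was 82 and 227 without isotype replicates 2 and 3, 63 without its own replicate 3, 95 after median centring, 269 with sample weights and 0 with only the 2 groups in the fit (limma, 192 at an unadjusted p under 0.05), and 26 of 49 named genes past the threshold kept their call whichever mouse was left out, among them Mmp9, Arg1, Cxcl9, the class II genes and 4 Fc receptor genes. Without the libraries of high low-end signal limma called 0 genes, with 163 at an unadjusted p under 0.05, while Cxcl9 stood at a log2 change of 3.25, Cd74 at 2.64 and Mmp9 at -2.80.

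**Figure D3:**
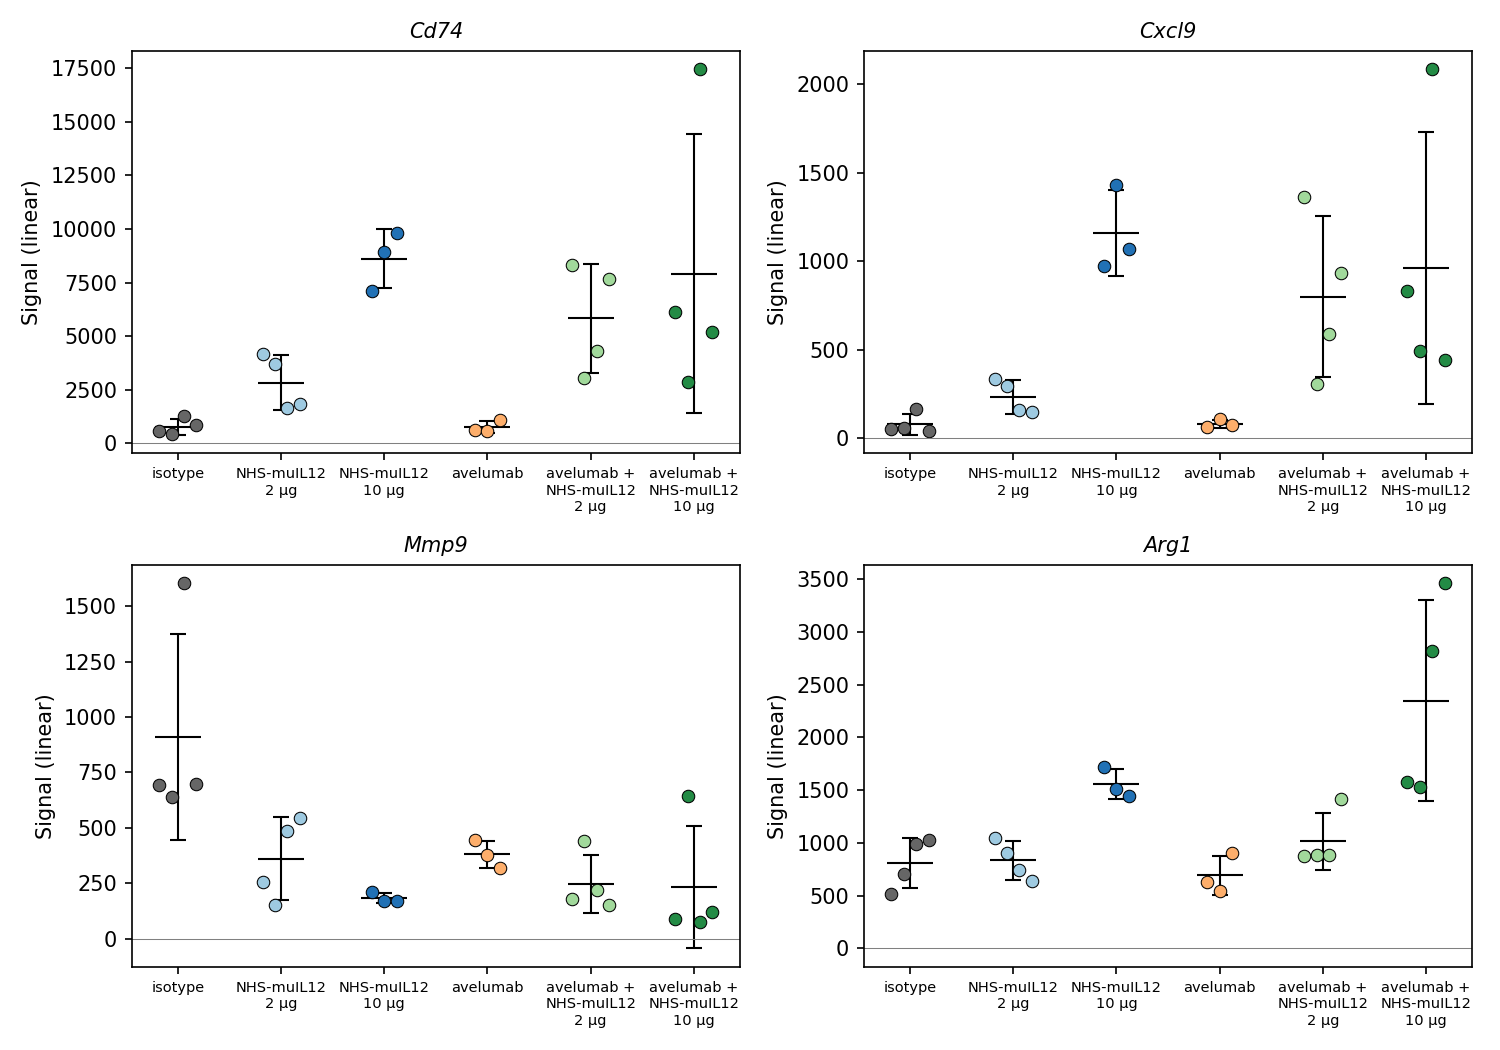
Signal of Cd74, Cxcl9, Mmp9 and Arg1 in single mice (linear scale) by treatment group; points are mice and bars the mean ± SD. Cd74 averaged 762 in isotype mice and 8614 with 10 µg NHS-muIL12. Mmp9 averaged 909 and 183 in these groups, a call lost in 5 of 7 fits with 1 mouse left out. The spread of Cxcl9 was widest in combination 10 µg (SD 768).

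Ifng was at 18.6 ± 15.9 (SD, n = 4) in isotype mice, 20.4 ± 22.1 (SD, n = 3) with 10 µg NHS-muIL12 and 9.11 ± 10.7 (SD, n = 4) in combination 10 µg, and did not pass against isotype in any group. Neither did Tbx21, Stat4, Cd8a, Cd4, Foxp3, Gzmb, Prf1, Pdcd1, Ido1, Il10 or Cr2. In combination 10 µg Cd8a was at 16.8 ± 23.3 (SD, n = 4) against 7.39 ± 10.8 (SD, n = 4), and Prf1 at 41.5 ± 17.6 (SD, n = 4) against 35.5 ± 30.6 (SD, n = 4). Il12rb1 was at 97.3 ± 33.0 (SD, n = 4) against 54.2 ± 20.6 (SD, n = 4), a log2 change of 0.85 ± 0.35 (limma adjusted p = 0.101). Socs1, a feedback inhibitor of cytokine signalling, was at 194 ± 125 (SD, n = 4) against 85.7 ± 13.8 (SD, n = 4), a change of 0.97 ± 0.37 (limma adjusted p = 0.0740). S100a8, a neutrophil and monocyte gene, was at 969 ± 270 (SD, n = 4) against 927 ± 311 (SD, n = 4).

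Each combination was compared with NHS-muIL12 alone at its dose to ask what avelumab added. At 2 µg, 2 genes passed in limma, both lower in the combination, and 83 had an unadjusted p under 0.05. Itga6, an integrin subunit, was at 200.0 ± 21.3 (SD, n = 4) against 348 ± 46.1 (SD, n = 4), a log2 change of -0.79 ± 0.15 (limma adjusted p = 0.0327). Tpsab1 was at 3.74 ± 1.95 (SD, n = 4) against 34.9 ± 22.5 (SD, n = 4), a change of -2.82 ± 0.57 (limma adjusted p = 0.0447). At 10 µg, 0 genes passed in limma, with 35 at an unadjusted p under 0.05, and the smallest adjusted p, 0.932, belonged to Cdkn1a (0.41 ± 0.14) and Nfatc3 (-0.38 ± 0.13). No list passed fry at either dose (smallest adjusted p in limma 0.341 and 0.941). The MHC class II score differed by 0.70 at 2 µg (95% interval -0.07 to 1.48) and by -0.51 at 10 µg (-1.35 to 0.32). The count of 2 was 0 or 1 whichever of the 8 mice was left out, 0 with the replicate number as a block, and 0 without the libraries of high low-end signal (limma, 66 at an unadjusted p under 0.05), and sample weights gave 50 genes.

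Against avelumab alone the combinations asked what NHS-muIL12 added. At 2 µg, 81 genes passed in limma, 72 higher and 9 lower, and 190 had an unadjusted p under 0.05. The largest rises were in Slamf7 (5.28 ± 1.17), C6, a terminal complement component (3.47 ± 1.00), Cxcl9 (3.08 ± 0.57), H2-Eb1 (3.08 ± 0.60) and H2-Aa (3.06 ± 0.60). The largest falls were in Tpsab1 (-2.30 ± 0.62), Aire (-2.24 ± 0.67), Elk1 (-1.98 ± 0.57), Fos (-1.03 ± 0.30) and F2rl1 (-1.02 ± 0.31). At 10 µg, 127 passed, 124 higher and 3 lower, and 215 had an unadjusted p under 0.05. Slamf7 (5.29 ± 1.17), C6 (4.14 ± 1.00), Ccl8 (3.47 ± 0.70), H2-Aa (3.40 ± 0.60) and H2-Ea-ps (3.35 ± 0.73) rose most, and F2rl1 (-1.22 ± 0.31), Mapk11 (-0.95 ± 0.32) and Itga6 (-0.61 ± 0.16) fell.

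Against avelumab alone, lists for MHC class II (6 of 10 rose at 2 µg and 6 at 10 µg), lymphocyte chemokines (5 and 7 of 13), Fc receptors (3 and 5 of 5), the interferon-gamma response (12 and 16 of 21), complement (7 and 11 of 22) and MHC class I (4 and 8 of 15) passed fry at both doses. Adjusted over the list alone, 7, 8, 5, 17, 12 and 6 members were higher at 2 µg and 7, 9, 5, 18, 14 and 10 at 10 µg. The largest of their adjusted p in limma was 0.0384 at 2 µg and 0.00615 at 10 µg. At 10 µg the macrophage list (11 of 19) and the type I interferon list (6 of 21) also passed. With an estimated correlation the adjusted p (camera in limma) was 0.667 for the 2 µg lists and 0.403 to 0.669 for the 10 µg lists, so no list call was kept.

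For these comparisons with avelumab the count of 81 was 0 without avelumab replicate 2 or 3 or without combination 2 µg replicate 1 or 4, 45 without combination 2 µg replicate 3, 217 with sample weights, 47 without the libraries of high low-end signal and 0 with only the 2 groups in the fit (limma, 198 at an unadjusted p under 0.05), and the 6 lists were 1 without avelumab replicate 2, 3 without avelumab replicate 3, 2 without combination 2 µg replicate 4 and 3 after median centring. The count of 127 was 52 and 63 without avelumab replicates 2 and 3, 61 without combination 10 µg replicate 3, 58 after median centring and 0 with only the 2 groups in the fit (limma, 166 at an unadjusted p under 0.05).

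The effects of avelumab and NHS-muIL12 together were also compared with the sum of their separate effects on the log2 scale. In limma 0 genes passed at 2 µg, with 37 at an unadjusted p under 0.05, the smallest adjusted p, 0.804, belonging to Il15ra (1.45 ± 0.42) and Itga6 (-0.78 ± 0.22). At 10 µg 0 genes passed in limma, with 16 at an unadjusted p under 0.05, the smallest adjusted p, 0.992, belonging to Lyve1 (3.88 ± 1.20) and Aire (-2.89 ± 0.95). Between the 2 combinations 0 genes passed in limma, with 35 at an unadjusted p under 0.05, the smallest adjusted p, 0.320, belonging to Arg1, higher at 10 µg by 1.15 ± 0.29, and Elk1 (2.11 ± 0.52). Averaged over the doses of NHS-muIL12, avelumab changed 0 genes in limma, with 128 at an unadjusted p under 0.05, the smallest adjusted p, 0.103, belonging to Tpsab1 (-1.65 ± 0.35) and Cdkn1a (0.33 ± 0.08). The averaged difference in list score was 0.02 for MHC class II (95% interval -0.45 to 0.49), -0.72 for neutrophils (-1.33 to -0.11) and -1.15 for type 2 and Th17 cytokines (-2.26 to -0.05). The interaction at 2 µg in the lymphocyte chemokine score was 0.74 (0.05 to 1.43), and these intervals are not adjusted for the number of lists. The 4 libraries of high low-end signal are all from mice without avelumab, and 14 of 15 type 2 and Th17 genes and 7 of 13 neutrophil genes had a mean signal under 50. Without those libraries the averaged difference was -0.23 for neutrophils (-0.67 to 0.21) and -0.25 for type 2 and Th17 cytokines (-1.05 to 0.54), the interaction at 2 µg in the chemokine score was 0.85 (-0.08 to 1.77), and limma called 0 genes for averaged avelumab, with 61 at an unadjusted p under 0.05. No list passed fry in these 4 comparisons (smallest adjusted p in limma 0.730, 0.953, 0.791 and 0.467), and for the averaged effect sample weights gave 136 genes, median centring 6 and quantile normalization 2.

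Scaling moved all genes together. Centring on each library's median shifted the median log2 change of all tested genes by -0.25 for 10 µg NHS-muIL12, 0.29 for avelumab, -0.13 for combination 2 µg and -0.19 for combination 10 µg, each against isotype, and by -0.43 and -0.49 for the combinations against avelumab. The balance of higher and lower calls depended on the scaling. Against isotype, quantile normalization gave 58 higher and 42 lower for 10 µg NHS-muIL12, 72 and 58 for combination 2 µg, and 91 and 104 for combination 10 µg. Median centring gave 39 and 4, 43 and 24, and 67 and 28 for the same groups. Against avelumab, combination 2 µg had 24 higher and 35 lower after median centring and 41 and 35 after quantile normalization, and combination 10 µg had 37 and 21, and 55 and 70. Among named genes past the threshold, 27 of 41, 26 of 32 and 40 of 49 kept their call under the 3 other scalings for 10 µg NHS-muIL12, combination 2 µg and combination 10 µg, and none past the threshold changed direction. Of these scalings, that by the housekeeping genes changed little and was a weak check. It shifted the median log2 change by 0.007, 0.004 and 0.012 for these groups, since the deposited housekeeping means already lay at 8.79 to 8.91. The MHC class II members past the threshold in combination 10 µg had a median change of 3.22 as deposited and 3.03 after centring.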

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

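The 3 tests of the class II rise, the 2 tests of the falls and the test of a swap were chosen only after the result was seen, while the split counts were planned. The test of dim signal was written before its own result was seen. Its mouse was picked by a list score, a measure added after the data were seen, so it was not fixed in advance of the data.

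The rise of MHC class II genes in combination 10 µg could come from uneven scaling, from more macrophages or from B cells and lymph node tissue. After centring on each library's median 6 of the 6 called class II genes stayed called. Centring moves all genes of a comparison by the same amount, here 0.19, against a median rise of 3.22 in these genes as deposited. A difference in library scale of this size was therefore excluded as the whole cause. Effects that differ between genes of a library, such as residual background, were not addressed. The class II score of bright members rose by more than the macrophage score of bright members. The lower end of the 95% interval for the difference was 0.736. This would exclude macrophage number with unchanged expression per cell only if the scores of both lists scale alike with cell number. Such scaling was not tested, so more macrophages stay open as a cause. The B cell score had an upper end of 1.00 against a lower end of 1.10 for class II, a narrow gap, and 14 of 15 B cell genes had a mean signal under 50, so B cells and lymph node tissue stay open.

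The falls in combination 10 µg could come from residual background in isotype replicates 1 and 2. For the 11 falls in genes with a mean signal under 50, the median log2 change was -2.04 against all isotype mice and -1.58 against isotype replicates 3 and 4 alone, while all 300 dim genes went from -0.75 to 0.20. Part of these falls may therefore be residual background, and this stays open. For the 8 falls in genes of at least 50, among them Mmp9, the median was -1.04 and -1.03, and all 8 stayed below 0. Residual background in those 2 mice therefore did not account for the median. Single genes moved both ways. Tab1 went from -0.55 to -0.29 and Itgb3 from -1.60 to -1.17, while Cdh5 went from -0.99 to -1.19 and Mmp9 from -2.47 to -2.80. The genes were picked as falls against the same isotype mice, so a part in single genes stays open. The rule for judging the dim genes was revised after the result was seen.

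NHS-muIL12 2 µg replicate 4 had an MHC class II score of 6.68, against 7.33 to 7.85 in the other mice of its group and 5.88 to 6.52 in isotype mice. A swap with an isotype mouse was tested by whether any isotype score reached 7.33, the lowest of the others in the group. The highest, 6.52, did not. The test assumes that every mouse given 2 µg reaches that score. If replicate 4 is labelled correctly, its 6.68 breaks this assumption, so a swap stays open. Over members with a mean signal of at least 50, replicate 4 scored 8.71. Isotype mice scored 7.09 to 7.95 over these members, and the other mice of its group 8.83 to 9.59. Dim signal of this library stays open, since over brighter members its score lay 0.118 below the lowest of its group, whose range was 0.761. A single wrong label or a missed dose was not tested.

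Mice were also divided in every other way between the 2 groups of a comparison, or at random for the interactions and averaged avelumab, to see whether chance can be excluded. Against isotype, 1 of 35 splits gave as many called genes as the real one for each of 10 µg NHS-muIL12 (79, highest other 35), combination 2 µg (71, highest other 1) and combination 10 µg (148, highest other 1). The same held for the combinations against avelumab (81, highest other 48, and 127, highest other 88). In these 5 comparisons the real split called more genes than any other. A share of 1 in 35 is the smallest that these splits can give. It was not adjusted for the number of comparisons, which also share mice. With only the compared groups in the fit, limma called 0 genes for combination 10 µg and for both combinations against avelumab (192, 198 and 166 at an unadjusted p under 0.05). The splits alone therefore do not exclude chance. For combination 2 µg against its NHS-muIL12 dose 1 of 35 splits also gave as many, but 2 genes against 1 in another split is too small a gap to lean on, and the count was 0 or 1 whichever mouse was left out. Where the real split called 0 genes in limma, with unadjusted counts of 16 to 128, all 35 or 100 splits gave as many by construction, so the counts say nothing about chance. The highest other split gave 162 genes for 2 µg NHS-muIL12, 76 for avelumab, 11 between the doses, 1 between the combinations, 1 for combination 10 µg against its NHS-muIL12 dose, 47 and 93 for the interactions and 80 for averaged avelumab. The split with 162 set isotype replicates 1 and 2 and NHS-muIL12 2 µg replicates 2 and 3 against the rest, and the split with 76 set isotype replicates 1 and 2 and avelumab replicate 3 against the rest. Both point to a structure of the samples apart from treatment, with isotype replicates 1 and 2 on one side. In both, that side held the libraries with the highest lower quartile of signal. It ran from 18.4 to 51.5 against 3.36 to 17.1 in the first split, and from 17.8 to 43.0 against 3.36 to 17.1 in the second.

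Single mice far from the rest of their group were counted with Dixon's test (critical value 0.829 for 4 mice) over 482 group values, and 39 passed. Chance alone gives about 0.05 of them for normal values. A mouse above others that are all at 0 passes whatever its value, so the 39 cannot be set against that share. Combination 10 µg replicate 3 had list scores of 5.69 for cytotoxic effectors (others 3.68 to 3.82), 8.98 for MHC class I (8.35 to 8.45), 6.24 for the interleukin-12 and Th1 axis (5.15 to 5.26) and 8.98 for lymphocyte chemokines (7.76 to 7.88). In it Tbx21 was at 28.1 (12.4 to 14.1), Nos2 at 198.7 (61.9 to 70.7), Tnfrsf14 at 370.2 (140.3 to 160.3) and Cd207 at 5.72 (all others 0). In combination 10 µg replicate 1, S100a8 was at 568.6 (1068 to 1157), Itgb3 at 18.4 (46.1 to 52.2), Fos at 172.2 (318 to 349), Mapk11 at 15.4 (27.2 to 30.1) and Mst1r at 0 (9.34 to 13.9).

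NHS-muIL12 2 µg replicate 4 had list scores of 6.92 for the type I interferon response (7.64 to 7.74) and 6.92 for lymphocyte chemokines (7.43 to 7.50), with Fpr2 at 63.7 (121.6 to 132.6) and Irf7 at 122.3 (237.7 to 255.5). Irf1 was at 1262 in replicate 1 of this group (882 to 931). Il12rb2 was at 0.434 and Sh2d1a at 1.10 in replicate 2, each with all others at 0. In replicate 3 Il12rb1 was at 96.5 (40.3 to 44.2), Lyve1 at 68.2 (36.3 to 38.4) and Klra6 at 5.29 (all others 0). In combination 2 µg replicate 1 the NK cell score was 2.14 (2.56 to 2.61), Ncr1 was at 38.8 (16.4 to 17.8) and Pnma1 at 3.34 (6.04 to 6.66). Slamf7 was at 12.3 in combination 2 µg replicate 2 (78.4 to 80.7). In combination 2 µg replicate 4 Arg1 was at 1416 (879 to 883), Nos2 at 84.9 (28.3 to 31.9) and Gpr183 at 41.5 (67.0 to 72.3).

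Isotype replicate 1 had a housekeeping mean log2 of 8.90 (8.85 in the others). Slamf6 was at 3.50 in isotype replicate 2 and at 0 in the others. In isotype replicate 3 the complement score was 6.55 (6.98 to 7.04) and Mmp9 was at 1605 (640 to 699). In isotype replicate 4 Cd274 was at 129 (206.3 to 225.5), Itgb3 at 49.1 (151 to 175), Il15ra at 27.0 (34.7 to 36.0) and Klra5 at 6.43 (0 to 0.0114). The housekeeping gene G6pdx was higher in combination 10 µg by a log2 change of 0.77 ± 0.13 (limma adjusted p = 4.68e-05), Polr1b was lower (-0.50, limma adjusted p = 0.00481) and Eef1g was lower (-0.31, limma adjusted p = 0.0212).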

How the results depend on the processing

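The tests on the same data under other settings were planned, except the pseudocount of 50 and the fit without 4 libraries, which were chosen only after the data were seen. With 3 or 4 mice per group, counts of genes past a threshold moved easily, no named gene past the threshold changed direction in any setting, and the cause of a moved count was not tested unless named. Counts are genes past the threshold in limma, in the 6-group fit 79 for 10 µg NHS-muIL12, 71 for combination 2 µg and 148 for combination 10 µg, each against isotype.

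Median centring gave 43 for 10 µg NHS-muIL12, 95 for combination 10 µg, 58 for combination 10 µg against avelumab and 6 for averaged avelumab. The higher share of calls went from 87.2% to 70.5% in combination 10 µg and from 97.6% to 63.8% against avelumab, since centring lowers all genes together there. Quantile normalization gave 130 for combination 2 µg and 2 for averaged avelumab, and a higher share of 46.7% of 195 calls in combination 10 µg. For 2 µg NHS-muIL12, 1 gene passed with the filter, 1 with a pseudocount of 10 and 1 with a pseudocount of 50. Sample weights gave 90 for 2 µg NHS-muIL12, 255 for 10 µg, 98 for avelumab, 308 for combination 2 µg, 269 for combination 10 µg, 63 between the doses, 50 for combination 2 µg against its NHS-muIL12 dose, 217 for combination 2 µg against avelumab and 136 for averaged avelumab. The trended and robust prior gave 1 for combination 2 µg against its NHS-muIL12 dose, and so did the pseudocounts of 10 and 50.

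With the replicate number as a block that comparison had 0 in limma, with 79 at an unadjusted p under 0.05. Residuals of mice with the same number had a mean r of -0.02 over 50 pairs, from -0.83 to 0.68, against 0.01 over 151 pairs with different numbers. With only the compared groups in the fit, limma gave 65 for 10 µg NHS-muIL12, 16 for combination 2 µg and 1 between the doses. It gave 0 for combination 10 µg (192 at an unadjusted p under 0.05), 0 for combination 2 µg against its NHS-muIL12 dose (81 unadjusted) and 0 for the combinations against avelumab (198 and 166 unadjusted). Fewer degrees of freedom remain in all of these fits. The fit of 10 µg NHS-muIL12 has fewer mice than that of combination 10 µg and still kept calls. Fewer degrees of freedom alone therefore do not explain the loss in combination 10 µg. In some lists this group's own spread was wider than that of other groups, and the 6-group fit pools the spread over all groups. The SD of its MHC class II score was 0.84, against 0.19 with 10 µg NHS-muIL12 and 0.27 in isotype mice. For the B cell score it was narrower, at 0.60 against 1.14 and 1.89. Whether spread caused the loss was not tested. Without the 4 libraries of high low-end signal limma gave 47 for combination 2 µg against avelumab, whose groups lose no mouse and where the cause was not tested. It gave 0 for 10 µg NHS-muIL12 (111 at an unadjusted p under 0.05), 0 for combination 2 µg (107), 0 for combination 10 µg (163) and 0 for combination 2 µg against its NHS-muIL12 dose (66), with fewer mice in the isotype and NHS-muIL12 groups.

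Of the 26 lists, fry called 1 for 2 µg NHS-muIL12 under median centring and 1 under quantile normalization. It called 9 and 10 for combination 2 µg under these, and 11 for combination 10 µg under quantile normalization. Without the 4 libraries it called 1 for 10 µg NHS-muIL12 and 0 for combination 2 µg. Camera with the preset correlation called 5 for 2 µg NHS-muIL12, 8 for 10 µg, 10 for combination 2 µg and 10 for combination 10 µg. With that preset it called 8 between the doses, and 10 and 11 for the combinations against avelumab. Where fry called none, it also called 4 for combination 2 µg and 2 for combination 10 µg against their NHS-muIL12 doses, 5 between the combinations, 2 for the interaction at 2 µg and 4 for averaged avelumab. With the estimated correlation camera called 0 for 10 µg NHS-muIL12, 0 for combination 2 µg and 0 for combination 10 µg.

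Leaving out each mouse in turn gave 0 to 1 genes for 2 µg NHS-muIL12, 23 to 90 for 10 µg, 0 to 1 for avelumab, 16 to 140 for combination 2 µg and 63 to 227 for combination 10 µg. It gave 0 to 0 between the doses and between the combinations, 0 to 1 for combination 2 µg against its NHS-muIL12 dose, 0 to 0 for combination 10 µg against its own, 0 to 95 and 52 to 144 for the combinations against avelumab, 0 to 0 for both interactions and 0 to 3 for averaged avelumab. Lists numbered 0 to 1 for 2 µg NHS-muIL12, 5 to 6 for 10 µg, 0 to 0 for avelumab, 1 to 7 for combination 2 µg and 6 to 9 for combination 10 µg. They numbered 1 to 7 and 6 to 8 for these combinations against avelumab, and 0 to 4 between the doses.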

Other observations

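None of the values here rests on a test chosen only after the result was seen. Beyond the comparisons already described, Ccl8, a chemokine of monocytes and macrophages, had a mean signal of 889 in isotype mice, 436 with avelumab, 3004 with 10 µg NHS-muIL12 and 5023 in combination 10 µg. C6 was at 37.8, 7.75, 78.4 and 161 in these groups. Cdh5, the cadherin of endothelial junctions, fell in combination 10 µg by a log2 change of -0.99 ± 0.25 (limma adjusted p = 0.0116), from 260.0 to 132.

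In some lists that passed no test the median, the mean and the direction in fry differed in sign. Against isotype these were CD4 and regulatory T cells, MHC class I and the interleukin-12 and Th1 axis for 2 µg NHS-muIL12, and T cells, neutrophils, dendritic cells and costimulation for 10 µg. They were MHC class I, MHC class II and cell death receptors for avelumab, and T cells, CD8 T cells, NK cells, lymph node, the interleukin-12 and Th1 axis and cell death receptors for combination 2 µg. In combination 10 µg it was inhibitory checkpoints. Between doses they were CD4 and regulatory T cells and dendritic cells, and between combinations T cells, mast cells and eosinophils, MHC class II and inhibitory checkpoints. Against NHS-muIL12 alone they were NK cells and inhibitory checkpoints at 2 µg, and MHC class I and cell death receptors at 10 µg. Against avelumab they were CD8 T cells, CD4 and regulatory T cells, stroma and endothelium, and epithelial genes at 2 µg, and neutrophils at 10 µg. For the interactions they were CD8 T cells and epithelial genes at 2 µg and NK cells and mast cells and eosinophils at 10 µg. For averaged avelumab they were macrophages, lymphocyte chemokines and cell death receptors.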
